A study of Arabidopsis thaliana with 9 samples.

How the data were processed

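Messenger RNA was measured by sequencing in 9 libraries from dissected inflorescence meristems of Arabidopsis thaliana, 3 libraries for each of 3 genotypes. The genotypes were the wild type (col-0), the mutant csld5, and the mutant carrying a transgene that expresses CSLD5 from the ATML1 promoter (pATML1::GFP+CSLD5-csld5), called complemented here. Groups and replicate numbers were taken from the sample titles. Nothing in the sources used here says whether the 3 libraries of a genotype came from separate plants or batches, so p-values measure the spread between these libraries.

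The authors deposited raw read counts per gene and, for the same genes, TPM (length-scaled transcript abundance). Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.6 and the TAIR10 assembly are named per the submitters' processing notes. The settings, the annotation release, the strand setting and the tool that made the TPM values are not given in the sources used here, so reads from overlapping or antisense genes may be counted at either gene. The count table lists 25760 genes. Of its columns, the one of col-0 replicate 1 holds 0 genes without a read, against 932 to 1540 in each of the other 8, so genes without a read in that library were not analysed here. The TPM table has 8616 missing cells, of which 643 fall where the count is above 0, and 1783 values where the count is 0. The deposited TPM values and counts therefore do not come from a single counting step. Missing TPM cells were set to 0 where TPM was used.

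Total counts ranged from 35543318 to 45679471 per library, and a floor of 3 counts was used for genes without reads. Floors cover counting error only. Positions, exon lengths and GC content were taken from the RefSeq annotation of TAIR10.1, in which 25637 of the listed genes have a model.

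Genes were tested with edgeR 4.0.16 in R 4.3.3: its default expression filter kept 22671 genes, TMM factors were applied, and the quasi-likelihood F test was run on a single fit of all 9 libraries with genotype as the only term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, with no fold minimum. Errors of log2 fold changes are standard errors from the same test, and errors of expression levels are standard deviations over 3 libraries. The 3 comparisons were csld5 against col-0, complemented against csld5, and complemented against col-0. A gene called in the first and called with the opposite sign in the second is said to have moved back. Because these comparisons share the csld5 libraries, the count was set beside 20 simulations in which the complemented libraries had the csld5 means, and beside the overlap of independent lists.

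For 19 gene lists, fixed before the data were examined, the list test was camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over all 57 tests. The same test with an estimated correlation, and fry, were run beside it. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. The lists cover cellulose synthase and synthase-like genes, pectin genes, expansin and xyloglucan genes, stem cell regulators, organ boundary and primordium regulators, cytokinin, auxin, gibberellin and brassinosteroid genes, mitosis, S phase, epidermis and cuticle, wall integrity and defence, wound and touch, heat shock, floral organ identity, anther and tapetum, vascular tissue, photosynthesis, and the clock. A list of 30 late pollen genes was written after the largest changes had been seen.

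The genes named were set by a rule fixed before the data were examined: CSLD5, its relatives CSLD1, CSLD2, CSLD3, CSLD4 and CSLD6, ATML1, WUS, CLV3 and STM; in each comparison the 8 largest rises and 8 largest falls among called nuclear genes whose 3 libraries all lay on one side of the other genotype's and whose average log2 CPM was at least 1; up to 4 called members of each list with the smallest p; and the 10 genes that moved back by the largest amounts. Genes named outside the rule are marked as such.

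Alternatives set before the data were examined were DESeq2 size factors, library totals without factors, no filter beyond 1 count in total, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2 TPM with pseudocounts of 1 and 0.1 (1 TPM in 3 libraries, or no filter), the replicate number as a block, fits of 2 genotypes at a time, a log2 fold change of at least 1, and leaving out each library. A correction for GC content and length was added after the data had been seen: a smooth curve on exon GC percent and log2 exon length (mgcv 1.9.3, values bounded at percentiles 1 and 99) was fitted to each library's deviation in log2 CPM (prior count 2) and used as an offset, for the 22580 tested genes with these values. Organelle genes have none there and are left as they were.

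The steps were tested on simulated data with 200 changed genes among 22318, all drawn from genes at 1 CPM or more in col-0. The edgeR test recovered 85.0% of them in csld5 against col-0 with 6 false calls, and 62.7% of those changed by 0.5 on the log2 scale. With the changes placed in the complemented libraries alone, 83.5% were recovered in complemented against col-0 with 13 false calls, and 59.7% of those changed by 0.5. Counts simulated from the fitted GC and length curves alone, with no gene changed, gave 3105 calls in csld5 against col-0 and 4600 in complemented against csld5, and 0 in both after the correction.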

Results

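Transcript levels were measured in inflorescence meristems of 3 genotypes, with 3 libraries each. CSLD5 encodes a cellulose synthase-like protein, and the series asks how it acts through the cell wall on stem cell activity. Total counts ran from 35543318 (col-0 replicate 3) to 45679471 (complemented replicate 3). Within a genotype, log2 levels correlated across genes at 0.9873 to 0.9909. The csld5 libraries stood apart from the other 6 on the first principal component, which held 49.7% of the variance.

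CSLD5 (AT1G02730, chromosome 1, 594502 to 598657, TAIR10.1) followed the genotype in every library. Its normalised level was 130.9 ± 4.35 CPM in col-0, 27.3 ± 0.726 CPM in csld5 and 935 ± 78.3 CPM in complemented plants (mean ± SD, n = 3), or 20.8% and 714% of the col-0 mean in csld5 and complemented. Reads of the transgene's coding sequence may be counted at this gene, and were not told apart from reads of the endogenous gene. In deposited TPM the means were 57.1 ± 2.73, 11.3 ± 0.394 and 399 ± 34.4. The log2 fold change was -2.26 ± 0.07 in csld5 against col-0, and 5.10 ± 0.08 in complemented against csld5.

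**Figure D1:**
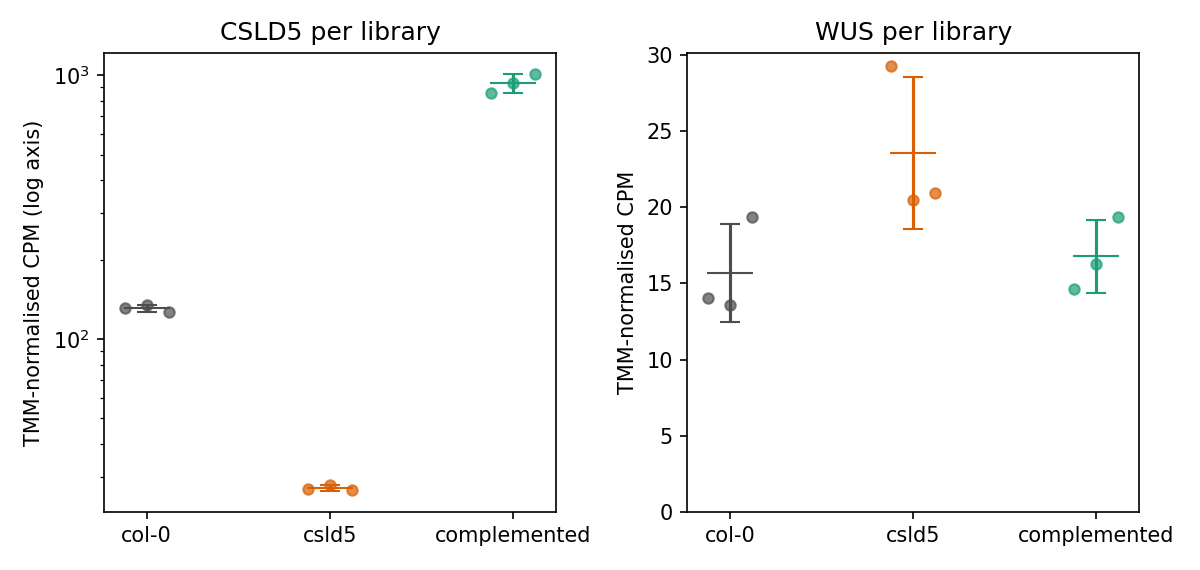
Normalised counts (CPM) of CSLD5 (left, log axis) and WUS (right) in each library (points), with the mean and SD of the 3 libraries of each genotype (bars). The complemented mean of CSLD5, 935 CPM, lies above the col-0 mean of 130.9 CPM, and WUS is highest in csld5.

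The first comparison asks which transcripts differ in the mutant. In csld5, 23 of the 26 cellulose synthase and synthase-like genes were higher than in col-0 and 0 were lower. Genes of the cytokinin list fell, 11 of 25 against 1 that rose, and so did 7 of the 15 regulators of organ boundaries and primordia, with 0 higher. Transcripts encoded in the chloroplast fell, 68 of the 82 tested, by a median of -1.93 on the log2 scale (quartiles -2.84 and -1.24). They took a very small share of counts: 0.021% to 0.0267% in col-0, 0.00734% to 0.00815% in csld5 and 0.0247% to 0.0329% in complemented libraries. All chloroplast genes together had 2826 to 3090 reads in a csld5 library, so fold changes of single chloroplast genes rest on few reads.

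Among the cellulose synthase genes, CESA8, a secondary wall subunit, rose by 0.79 ± 0.10 (log2, SE, n = 3 against 3), CESA6, a primary wall subunit, by 0.55 ± 0.07, and CSI1, which links the complexes to microtubules, by 0.79 ± 0.10. After a correction for GC content and length CESA6 stood at 0.32 and CSI1 at 0.36. Of the nearest relatives of CSLD5, CSLD1 rose by 2.17 ± 0.40 (1.06 ± 0.321 CPM in col-0, 4.75 ± 2.79 CPM in csld5) and CSLD4 by 1.79 ± 0.26 (2.56 ± 0.539 and 8.91 ± 3.20 CPM). Late pollen genes, a list written after the largest changes had been seen, rose in the same comparison in 14 of 28 cases and fell in 1, and the source of the rise in CSLD1 and CSLD4 was not tested. CSLD2 (0.38 ± 0.08), CSLD3 (0.31 ± 0.07) and CSLD6 (0.49 ± 0.17) were called too, but with this correction their values were 0.05, -0.03 and 0.17 and none was called. The call of CSLD6 was also lost without any 1 of the col-0 replicates (0.52, 0.52 and 0.46 without replicates 1, 2 and 3), without csld5 replicate 3 (0.35), with library totals (0.41), and with limma on TPM (0.36 to 0.49). The list's median was 0.42, with an adjusted p of 3.2e-08 by camera (limma, Benjamini-Hochberg) and an adjusted p = 0.46 with an estimated correlation. Adjusted over the list alone, 23 genes were called. After the GC and length correction 16 were higher and 0 lower.

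Of 31 expansin and xyloglucan-modifying genes, 14 rose and 6 fell (15 and 6 adjusted over the list alone). The wall-loosening expansins EXPA11 (2.48 ± 0.20), EXPA8 (1.5 ± 0.10), EXPA1 (0.99 ± 0.08) and EXPA3 (0.88 ± 0.08) rose. Set apart after the values were seen, 9 of 13 expansins rose and 0 fell, while 3 of 14 XTH genes, which cut and join xyloglucan, rose and 6 fell. The list's median was 0.18 (camera adjusted p = 0.023, limma with Benjamini-Hochberg adjustment; adjusted p = 0.47 with an estimated correlation). Of 19 pectin genes 12 rose and 2 fell, the same numbers as adjusted over the list alone, with PME5 at 0.68 ± 0.07 and PGX3, a polygalacturonase, at 0.65 ± 0.11 (0.39 after the GC and length correction), while the methylesterase PME41 fell by 0.72 ± 0.13. Its camera adjusted p was 0.0096 (limma, Benjamini-Hochberg), the adjusted p = 0.46 with an estimated correlation, and 0.15 after the GC and length correction, which ended the call.

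Epidermal and cuticle genes rose in 17 cases and fell in 1 of 29 (20 and 1 adjusted over the list alone). Examples are GPAT6, an enzyme of cutin synthesis (1.16 ± 0.11), CER2 (0.90 ± 0.11) and CER6 (0.55 ± 0.07), enzymes of wax synthesis, and ABCG11, a cuticle lipid transporter (0.50 ± 0.06, and 0.32 after the GC and length correction). The median was 0.28, and 0.06 after the GC and length correction (camera adjusted p = 5.2e-05, limma with Benjamini-Hochberg adjustment; adjusted p = 0.52 with an estimated correlation). ATML1, the regulator whose promoter drives the transgene, differed by 0.14 ± 0.07 and was not called (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.12), though it was without csld5 replicate 2 (0.20). Of 19 nuclear photosynthesis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), LHCB4.1 by 0.62 ± 0.05 (after the GC and length correction 4 were higher and 1 lower, and LHCB4.1 stood at 0.26). Its camera adjusted p was 0.0031 (limma, Benjamini-Hochberg), the adjusted p = 0.51 with an estimated correlation, and 0.60 after the GC and length correction, which ended the call.

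In the cytokinin list, the type-A response regulators, primary targets of cytokinin signalling, fell: ARR7 by 1.15 ± 0.10, ARR15 by 1.03 ± 0.12, ARR9 by 0.90 ± 0.08 and ARR5 by 0.87 ± 0.10 (ARR9 -0.58 and ARR5 -0.57 after the GC and length correction). Grouped after the values were seen, 8 of 8 tested type-A regulators fell, and 7 after the GC and length correction. For the whole list the counts were 2 higher and 12 lower adjusted over the list alone, the median was -0.27, the camera adjusted p was 0.00082 (limma, Benjamini-Hochberg), and the adjusted p = 0.30 with an estimated correlation. Among the boundary and primordium regulators, ANT, which promotes organ growth, fell by 0.57 ± 0.06, FIL, a marker of organ polarity, by 0.62 ± 0.08, CUC3, a boundary gene, by 0.69 ± 0.15, and RAX1 changed by -1.93 ± 0.43. Adjusted over the list alone the counts were the same, the median was -0.38, the camera adjusted p was 0.0085 (limma, Benjamini-Hochberg), and the adjusted p = 0.32 with an estimated correlation.

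Of 24 mitosis and cytokinesis genes 2 rose and 11 fell (2 and 13 adjusted over the list alone), among them the cyclins CYCA1;1 (-0.55 ± 0.06) and CYCB2;2 (-0.44 ± 0.08). The median was -0.18 (camera adjusted p = 0.044, limma with Benjamini-Hochberg adjustment; adjusted p = 0.51 with an estimated correlation, 0.063 with the replicate number as a block and 0.05 with DESeq2 size factors, each of which ended the call). S-phase genes fell in 7 of 14 cases with 0 higher (8 lower and 1 higher adjusted over the list alone), MCM2, a replicative helicase subunit, by 0.28 ± 0.06 (-0.44 after the GC and length correction), and the list was not called (camera adjusted p = 0.074, limma with Benjamini-Hochberg adjustment), though it was after that correction (0.00089, with 10 lower and 0 higher; adjusted p = 0.47 with an estimated correlation). Floral organ identity genes fell in 6 of 13 cases with 0 higher (7 lower adjusted over the list alone), STK by 0.52 ± 0.06 (-0.31 after the GC and length correction) and SEP1 by 0.42 ± 0.06. Its camera adjusted p was 0.028 (limma, Benjamini-Hochberg), the adjusted p = 0.54 with an estimated correlation, and 0.59 after the GC and length correction, which ended the call.

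Among 22 stem cell and meristem regulators 9 rose and 4 fell (9 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.32, limma with Benjamini-Hochberg adjustment). With the GC and length correction 4 were higher and 5 lower, and the median turned from 0.09 to -0.06. WUS, the gene that specifies the stem cell niche, rose by 0.59 ± 0.16 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0093), from 13.6 to 19.4 CPM in the col-0 libraries to 20.5 to 29.3 CPM in the csld5 libraries. HAM3 rose by 0.76 ± 0.10 (0.28 after the GC and length correction) and the receptor kinase BAM1 by 0.46 ± 0.09 (0.15, no longer called). STM, which maintains the meristem, rose by 0.18 ± 0.06, a call lost after the correction (0.10), with library totals (0.10), with limma on TPM (0.11 to 0.12), without col-0 replicate 2 (0.16) or 3 (0.18), and without csld5 replicate 2 (0.17). CLV3, the stem cell peptide gene, had 6 reads or fewer over the 3 libraries of any genotype and was not tested.

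The other lists were not called by camera. Fry called the auxin and the wound and touch lists downward (adjusted p = 0.045 and 0.034), and the vascular and clock lists upward (0.034 and 0.029). Auxin genes rose in 8 and fell in 8 of 31 cases (8 and 9 adjusted over the list alone), but in 3 and 11 after the GC and length correction, which moved the median from -0.09 to -0.20, with the carrier AUX1 at 0.61 ± 0.07 and GH3.6 at -0.57 ± 0.07. Wound and touch genes rose in 6 and fell in 10 of 20 cases (7 and 10 adjusted over the list alone), with the calmodulin-like CML24 at -1.54 ± 0.08 and the early stress regulator ERF104 at -1.85 ± 0.25. Defence genes rose in 4 and fell in 4 of 20 cases, also adjusted over the list alone, with PR2 at 1.95 ± 0.18, PR5 at 1.64 ± 0.14 and WRKY53 at -2.10 ± 0.28, and the list's mean (-0.14) had the opposite sign of its median (0.20). Gibberellin and brassinosteroid genes rose in 4 and fell in 2 of 14 cases (4 and 3 adjusted over the list alone), heat shock genes rose in 2 and fell in 0 of 9 (1 and 0), vascular markers in 2 and 0 of 11 (2 and 0), and clock genes in 6 and 2 of 12 (6 and 2). With the GC and length correction the counts were 0 higher and 1 lower for heat shock, 1 and 0 for vascular, 3 and 2 for clock, 2 and 4 for defence, 6 and 9 for wound and touch, and 3 and 2 for gibberellin and brassinosteroid genes. Anther and tapetum markers rose in 2 and fell in 4 of 21 cases (2 and 3 adjusted over the list alone), with a median of 0.12 (-0.09 after the GC and length correction, with 2 higher and 1 lower) and a mean of -0.05.

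**Figure D2:**
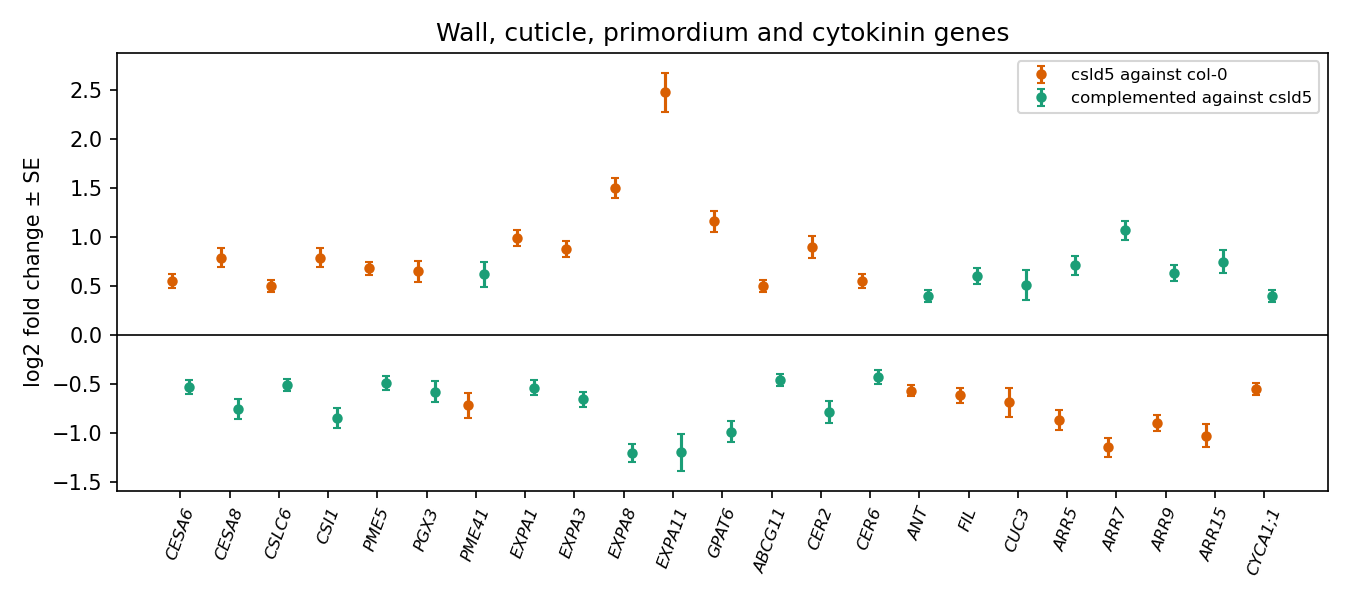
Log2 fold change with SE (vertical axis) of genes named by the rule, in csld5 against col-0 and in complemented against csld5, 3 libraries per genotype. Wall and cuticle genes such as EXPA8 (1.5 and -1.21) and cytokinin targets such as ARR7 (-1.15 and 1.07) take opposite signs in the comparisons.

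The largest rises in csld5 among nuclear genes that met the naming rule were those of AT1G27565 (5.99 ± 0.25), AT3G55870 (5.61 ± 0.70), AAE11 (5.41 ± 0.54), AT5G50040 (4.46 ± 0.43), AT3G05945 (4.45 ± 0.21), AT2G38240 (4.19 ± 0.32), GPAT5, an enzyme of suberin synthesis (4.05 ± 0.32), and AT3G22910 (3.73 ± 0.32). Their col-0 means ran from 0.108 CPM (AT3G55870) and 0.115 CPM (AT1G27565) to 8.54 CPM (AT3G22910). The largest of these fold changes thus rest on few col-0 reads. AT1G75945 had 2021 reads over the col-0 libraries and 0 over the csld5 libraries, and AT1G06957 had 956 and 0, which makes them at least 634-fold and 300-fold lower against a floor of 3 counts over the group. The next largest falls were those of AT5G28630 (-4.23 ± 0.42), AT3G01795 (-3.69 ± 0.17), AT1G49500 (-3.55 ± 0.17), AT5G36925 (-3.54 ± 0.45), AT1G08733 (-3.25 ± 0.24) and AT1G19020 (-3.02 ± 0.40).

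In all, edgeR called 9417 of 22671 genes in csld5 against col-0, 4790 higher and 4627 lower, with a median absolute log2 fold change of 0.43; 1536 of them changed by at least 1. With library totals in place of TMM factors the median of all genes moved to -0.10 and the counts to 3524 higher and 6394 lower, so directions of small changes are relative to the scaling. Fold changes followed the GC content (Spearman's rho = 0.40 across genes) and length (0.37) of the genes, which are not independent replicates, and 5524 of the called genes kept their call and sign among the 7511 called after the GC and length correction. Without csld5 replicate 3, whose deviation followed GC content and length most (R squared 0.339, against 0.0254 to 0.215 in the others), the corrected count was 5978 in place of 7511.

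**Figure D3:**
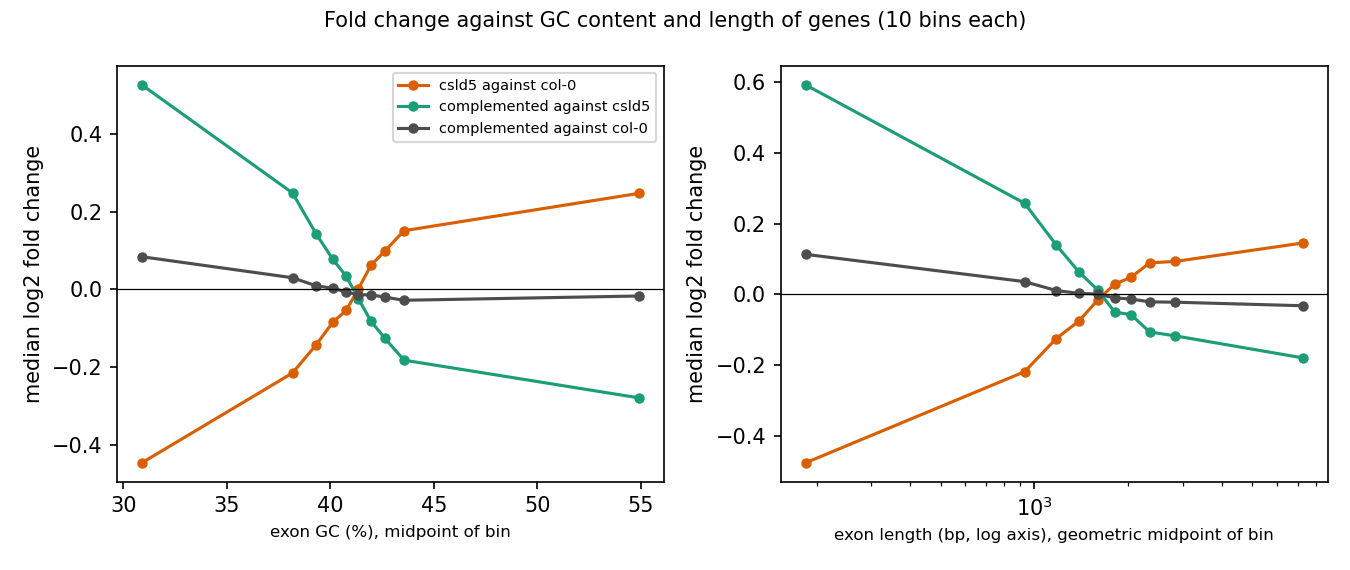
Median log2 fold change (vertical axis) of genes in 10 bins of exon GC percent (left) and of exon length (right, log axis), for the 3 comparisons. The lines of csld5 against col-0 rise with GC content and length, with rho of 0.40 and 0.37, and those of complemented against csld5 fall, with rho of -0.46 and -0.45.

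The second comparison asks which transcripts move when CSLD5 is expressed from the ATML1 promoter in the mutant. It shares the csld5 libraries with the first comparison, so a reversal in it is not an independent result. A feature of those libraries alone would reverse too. The GC and length trend was strongest there but not confined to them. Fold changes in complemented against col-0 also followed GC content (Spearman's rho = -0.13 across genes) and length (-0.18), with the sign opposite to csld5 against col-0. The wall, cytokinin and primordium genes moved the other way: 20 of 26 cellulose synthase genes fell and 0 rose (22 adjusted over the list alone), 10 of 25 cytokinin genes rose and 1 fell (11 and 2), and 8 of 15 boundary and primordium regulators rose and 0 fell (9 and 0). Cuticle genes fell in 15 of 29 cases and rose in 1 (17 and 1), photosynthesis genes fell in 13 of 19 and rose in 0 (14 and 0). After the GC and length correction 9 cuticle and 7 photosynthesis genes were lower, and the medians moved from -0.25 to -0.11 for cuticle, from -0.32 to -0.17 for photosynthesis, from -0.44 to -0.28 for cellulose synthase and from 0.28 to 0.17 for cytokinin genes. Chloroplast-encoded transcripts rose in 69 of 82 cases, by a median of 2.18.

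Examples are CSI1 (-0.85 ± 0.10), CSLA2, a mannan synthase (-0.45 ± 0.06), EXPA8 (-1.21 ± 0.09), XTH9 (0.54 ± 0.06), GPAT6 (-0.99 ± 0.11), ARR7 (1.07 ± 0.10), LOG1, a cytokinin-activating enzyme (0.98 ± 0.09), FIL (0.60 ± 0.08) and ANT (0.40 ± 0.06). After the GC and length correction CSI1 stood at -0.42, GPAT6 at -0.63, ARR7 at 0.67 and LOG1 at 0.40. ARR9 rose by 0.63 ± 0.08 and was no longer called after it (0.17). CSLD4 fell by 1.34 ± 0.25 (-0.88 after it). CSLD2 (-0.43 ± 0.08) and CSLD3 (-0.28 ± 0.07) were called, and after the correction took values of -0.09 and 0.07 and were not. CSLD1 (-0.83 ± 0.37) and CSLD6 (-0.37 ± 0.17) were not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.086 and 0.096), though CSLD1 was without csld5 replicate 1 (-1.17). The camera adjusted p was 2.8e-08 for the cellulose synthase list, 0.006 for cytokinin, 0.021 for boundary genes, 3.5e-05 for cuticle and 6.9e-08 for photosynthesis (limma, Benjamini-Hochberg). With an estimated correlation these became an adjusted p = 0.46, 0.32, 0.41, 0.51 and 0.46.

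Pectin genes rose in 2 and fell in 10 of 19 cases (2 and 10 adjusted over the list alone), expansin and xyloglucan genes rose in 4 and fell in 15 of 31 (4 and 15), defence genes in 3 and 9 of 20 (3 and 10), floral organ genes rose in 6 of 13 (6), and vascular markers fell in 6 of 11 (7). These lists were called with a camera adjusted p of 0.049, 0.021, 0.019, 0.01 and 0.021 (limma, Benjamini-Hochberg), and had an adjusted p = 0.47, 0.47, 0.50, 0.51 and 0.50 with an estimated correlation. Among their members PR2 fell by 3.08 ± 0.20, STK rose by 0.51 ± 0.06 (0.22 after the GC and length correction) and ATHB8, a procambium regulator, fell by 0.65 ± 0.09 (-0.28). The pectin call was lost with the replicate number as a block (0.065) and with DESeq2 size factors (0.05). After the GC and length correction the pectin (0.59), floral (0.59), vascular (0.12) and defence (0.05) lists were no longer called. It brought calls of the S-phase list (7 higher and 0 lower in place of 5 and 1 of 14, camera adjusted p = 0.0016 in place of 0.32, limma with Benjamini-Hochberg adjustment) and of the anther and tapetum list (9 and 1 in place of 6 and 1 of 21, 0.0016 in place of 0.074), which had an adjusted p = 0.50 and 0.68 with an estimated correlation. The mitosis list, called as falling in csld5, was not called here (5 of 24 higher and 3 lower, also adjusted over the list alone, median 0.04, camera adjusted p = 0.68, limma with Benjamini-Hochberg adjustment). Camera did not call the auxin (7 of 31 higher, 8 lower), gibberellin and brassinosteroid (2 of 14, 3), wound and touch (4 of 20, 3), heat shock (0 of 9, 2) and clock lists (1 of 12, 6) either. Their counts adjusted over the list alone were the same, except 3 higher for wound and touch. Fry called the heat shock and clock lists downward (adjusted p = 0.046 for each).

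Of the 22 stem cell and meristem regulators 2 rose and 10 fell in complemented against csld5, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.064, limma with Benjamini-Hochberg adjustment). With the GC and length correction 3 were higher and 5 lower, and the median went from -0.21 to 0. WUS fell by 0.49 ± 0.16 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.025), a call lost after the correction (-0.47), with library totals (-0.39), with limma on unfiltered TPM (-0.42), without csld5 replicate 1 (-0.31), and without complemented replicate 1 (-0.40) or 2 (-0.47). STM fell by 0.29 ± 0.06 and HAM3 by 0.86 ± 0.10 (-0.40 after the correction).

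**Figure D4:**
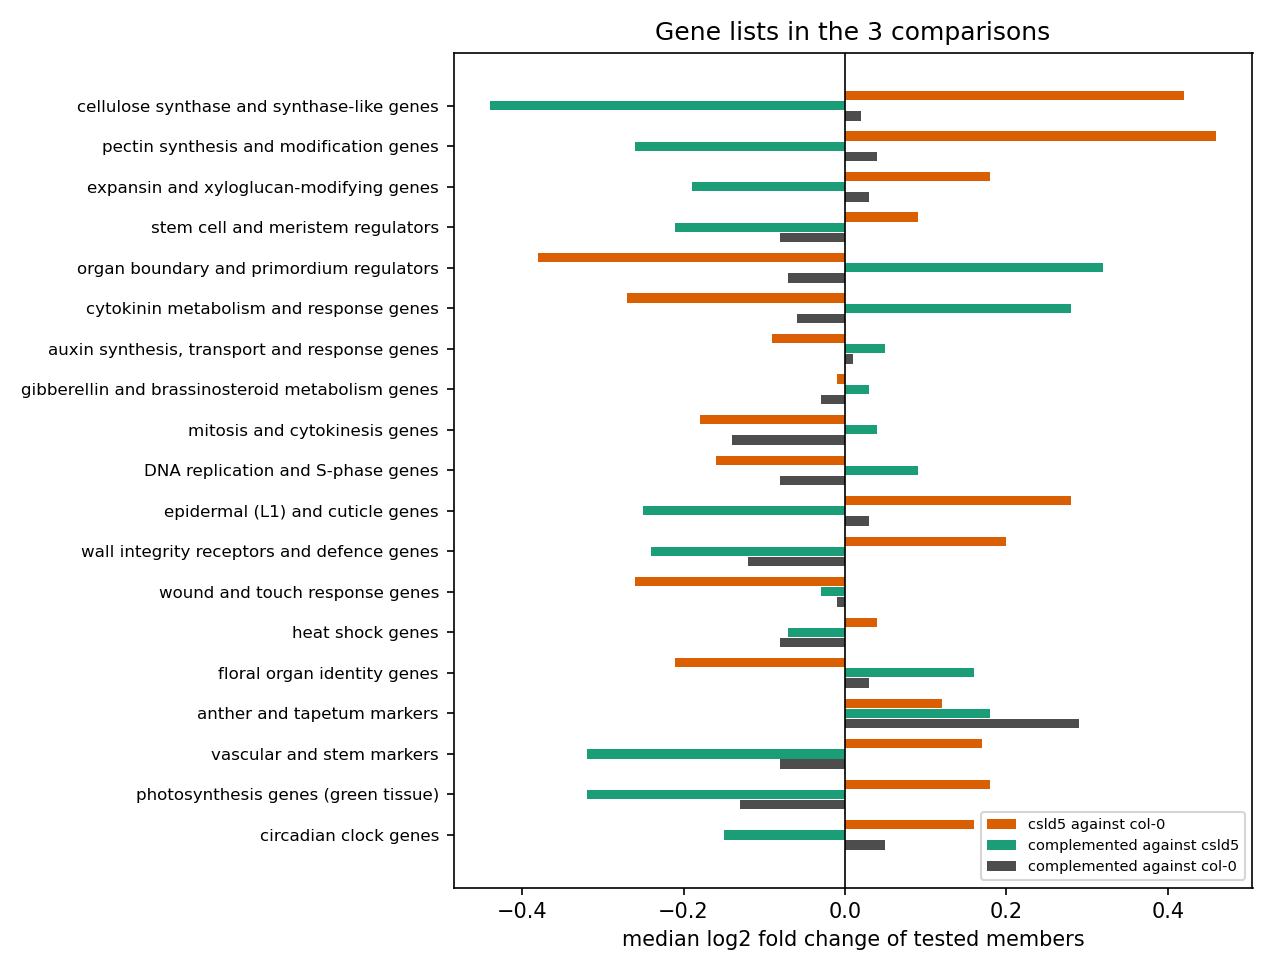
Median log2 fold change (horizontal axis) of the tested members of each of the 19 gene lists in the 3 comparisons (bars). The cellulose synthase list has medians of 0.42, -0.44 and 0.02, and the cytokinin list -0.27, 0.28 and -0.06.

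Among nuclear genes that met the expression limit of the naming rule, AT1G75945 had 0 reads over the csld5 libraries and 16 over the complemented libraries. This made it at least 4.84-fold higher against a floor of 3 counts over the group. It met the limit through col-0 (16.3 CPM) and stayed far lower in the complemented libraries (0.124 CPM). The largest rises after this gene and CSLD5 were those of AT5G28630 (5.01 ± 0.41), AT5G36925 (4.07 ± 0.44), AT3G01795 (3.98 ± 0.17), AT1G19020 (3.68 ± 0.39), PP2-A5 (2.85 ± 0.35) and AT1G05675 (2.65 ± 0.38), and the largest falls after PR2 those of AT5G19880 (-2.33 ± 0.43), GPAT5 (-2.16 ± 0.27), AAE11 (-2.12 ± 0.40) and ABCG6 (-1.99 ± 0.25). In all, edgeR called 9273 genes, 4500 higher and 4773 lower. With library totals the median of all genes was 0.11 and the counts were 6422 higher and 3171 lower. After the GC and length correction 6015 genes were called, 4307 of them among the 9273 with the same sign, and 4580 without csld5 replicate 3.

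Of the 9417 genes called in csld5, 7430 (78.9%) moved back in the complemented line. They include AT5G28630 (-4.23, then 5.01), AT3G01795 (-3.69, then 3.98), AT5G36925 (-3.54, then 4.07) and AT1G19020 (-3.02, then 3.68), and 65 of the 82 chloroplast genes, such as ATCG00220 (-6.38, then 6.41) and ATCG01020 (-3.22, then 3.62). Of the 7430, 3838 were higher in csld5 and 3592 lower, where independent lists would share 1008 and 918. With complemented libraries simulated at the csld5 means, 0.25 genes moved back on average over 20 simulations. Only 0.5 genes on average were called there in complemented against csld5. So few calls fix that number in advance, and it cannot show what the shared libraries add to the 7430. The covariance of the fold changes was -0.294, against -0.0257 in those simulations. They hold independent noise between libraries only, so this contrast does not cover a feature shared by the csld5 libraries and does not show restoration. Since 3 csld5 libraries cannot be split into parts of at least 2, some of the excess over independent lists may come from these shared libraries. After the GC and length correction 4697 genes moved back, 3376 of which did so before it too, and 3570 without csld5 replicate 3. Of 1536 genes changed by at least 1 in csld5, 812 moved back by at least 1.

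The third comparison asks which transcripts still differ between complemented and col-0 plants. Of the genes called in csld5, 9106 (96.7%) were not called here, and 0 of the 26 cellulose synthase, 25 cytokinin, 15 boundary, 22 stem cell and 29 cuticle genes were. Few genes of any kind were called here, 346 of 22671 (1.53%), so these shares alone do not show restoration. Adjusted over the list alone 3 cytokinin genes were lower and the other counts stayed at 0. CSLD1 stood at 1.34 ± 0.41 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.15), and was called with DESeq2 (adjusted p = 0.024) and in the edgeR fit of these 2 genotypes alone (0.044). A p that misses the threshold does not show equal levels: with simulated changes in the complemented libraries, 59.7% of those of 0.5 on the log2 scale were recovered in this comparison. That share covers only genes at 1 CPM or more in col-0. The genes that did differ include 22 neighbours on chromosome 1 and genes of early touch and stress responses.

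The run of 22 consecutive expressed genes lies between 24064822 and 24171635 on chromosome 1 (106.8 kb), 23.5 Mb from CSLD5. All 22 were lower than in col-0 both in complemented (median -1.60, quartiles -1.67 and -1.53) and in csld5 plants (median -1.62), and the median level over the run was 32.5% to 33.8% of col-0 in each of these 6 libraries. In csld5 the single genes ranged from -3.25 (AT1G08733) to -0.99 (ILA). AT1G64840 (-1.71 ± 0.06), HEB1 (-1.72 ± 0.08) and AT1G65032 (-1.73 ± 0.12) are examples in complemented against col-0. The expressed genes on either side, AMT1;2 and AT1G65070, differed by 0.02 each in complemented and by 0.27 and 0.13 in csld5 plants. ILA and these neighbours were picked out after their values were seen. The next longest run of called genes of one sign had 2 genes, and the longest in 100 shuffled orders of 18456 genes had 3.

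**Figure D5:**
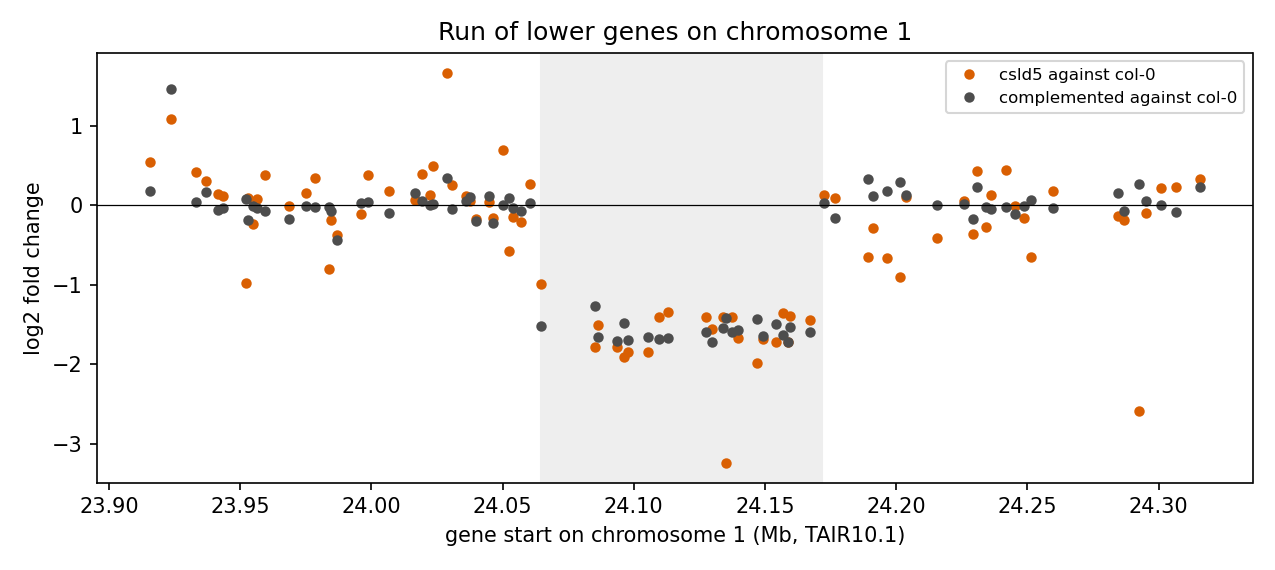
Log2 fold change (vertical axis) of expressed genes by start position on chromosome 1 (Mb, TAIR10.1), for csld5 and complemented against col-0; the shaded span is the run. The 22 genes in the span have medians of -1.62 and -1.60, and the 10 genes on each side have medians of -0.15 (csld5, SD 0.38) and 0.02 (complemented, SD 0.15).

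Among touch and stress genes, 4 of the 20 in the wound and touch list fell and 0 rose (8 and 5 adjusted over the list alone): ERF104 (-2.81 ± 0.26), ERF5 (-1.64 ± 0.19), ZAT10 (-1.39 ± 0.20) and ERF6 (-1.09 ± 0.20). The touch-induced XTH22 (-1.71 ± 0.22) and, among the largest falls, AT4G27280 (-1.90 ± 0.17) and CAF1a (-1.82 ± 0.16) were lower too. The call of ERF6 was lost without col-0 replicate 1 (-1.08) or 2 (-1.11) without complemented replicate 1 (-1.0) and with limma on unfiltered TPM (-1.09). The list had a camera adjusted p of 0.004 (limma, Benjamini-Hochberg), and an adjusted p = 0.47 with an estimated correlation. Its median was -0.01 and its mean -0.35, and fry did not call it (adjusted p = 0.094). Defence genes (1 of 20 lower, PR2 at -1.13 ± 0.21, and 5 lower and 1 higher adjusted over the list alone), mitosis genes (0 of 24), anther markers (0 of 21, 2 higher adjusted over the list alone) and photosynthesis genes (1 of 19 lower, 6 adjusted over the list alone) were called as lists, with camera adjusted p of 0.0037, 6e-04, 0.00021 and 3.5e-05 (limma, Benjamini-Hochberg), the anther list upward and the others downward. With an estimated correlation these had an adjusted p = 0.47, 0.46, 0.51 and 0.47. The call of PR2 was lost without col-0 replicate 1 (-1.08) or 2 (-0.98), without complemented replicate 1 (-1.14), and with limma on TPM with a pseudocount of 1 (-0.79).

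Genes higher in complemented plants than in col-0 included AT1G27565 (6.88 ± 0.24), AT3G05945 (5.22 ± 0.21), AT3G29633 (3.18 ± 0.18), AT2G08735 (3.15 ± 0.30) and AT5G35935 (3.03 ± 0.09), and EXPA11 (1.27 ± 0.20, a call lost with limma on unfiltered TPM, 1.15). AT1G75945 had 16 reads and AT1G06957 1 read over the complemented libraries. In all, edgeR called 346 genes, 215 higher and 131 lower, and 452 after the GC and length correction, 234 higher and 218 lower. Of the 346, 297 were called in csld5 against col-0 with the same sign, where independent lists would share 72.2. Part of that excess may come from the shared col-0 libraries. Simulated unchanged groups shared 0, but had only 0.25 calls in csld5 and 0.15 in complemented against col-0, so they cannot measure that part. The count of 346 fell to 139 without col-0 replicate 1, 170 without col-0 replicate 2 and 154 without complemented replicate 1, and was 663 with DESeq2 and 137 to 217 with limma on TPM.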

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

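The GC and length corrections, alone and without csld5 replicate 3, were chosen after the data had been seen; the other alternatives were set before. CSLD5 kept its direction and call in each alternative looked up for it. The fold minimum and the correction without csld5 replicate 3 were not among these. When 1 library was left out, CSLD5 ranged from -2.29 to -2.24 in csld5 against col-0 and from 5.04 to 5.16 in complemented against csld5. Leaving out 1 library gave 7403 to 9451 genes in csld5 against col-0, 7354 to 9412 in complemented against csld5, 139 to 415 in complemented against col-0, and 6140 to 7689 moved back. A log2 fold change of at least 1 left 1536, 1233 and 199 genes in the 3 comparisons and 812 moved back, which follows from the stricter rule. The GC and length correction gave 7511 genes in csld5 against col-0, 6015 in complemented against csld5 and 4697 moved back. Without csld5 replicate 3 these 3 counts were 5978, 4580 and 3570. In complemented against col-0, DESeq2 called 663 genes, and limma on TPM 211 (pseudocount 1), 217 (0.1) and 137 (no filter); the cause was not tested. With the replicate number as a block the counts were 9540, 9504 and 368 genes, 7613 moved back and 22 list calls; deviations of libraries with the same number correlated at -0.11 to 0.20, over 0.1 in 1 of 9 pairs, so the numbers were not taken to pair the libraries.

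Of the 57 list tests, 24 were called by camera (limma) with the preset correlation, 0 with an estimated one (5 at an unadjusted p under 0.05, lowest adjusted p 0.3), 33 by fry, and 20 after the GC and length correction. Among the named genes and comparisons, that correction ended 34 of 247 results and turned 4: CSLD3 (-0.03 in csld5 against col-0, 0.07 in complemented against csld5), MCM4 (0.06) and SUC2 (0.03), both in complemented against csld5. The correction removes the trend by construction, and whether the part removed was bias or an effect of genotype was not tested. CLV3, with at most 4 reads in a library, had too few to be compared, and the cause was not tested.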

Other observations

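All tests of explanations below, and the list of late pollen genes, were chosen after the results were seen. Of 28 late pollen genes tested, 14 were higher and 1 lower in csld5 than in col-0 (edgeR), with a median log2 fold change of 0.52 (quartiles 0.09 and 1.23), and 17 and 0 after the GC and length correction (median 0.61). The 8 most abundant ranged from -0.23 to 1.39. In complemented against col-0, 2 were higher and 0 lower, with a median of 0.35. CLV3 had 6 reads over the col-0 libraries, 0 over the csld5 libraries and 4 over the complemented libraries, too few for a comparison.

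AT1G75945 and AT1G06957, with 2021 and 956 reads over the col-0 libraries, had 0 reads in csld5 and 16 and 1 in the complemented line. They lie at 28515245 and 13477922 on chromosome 1, outside the run of lower genes. Mitochondrial transcripts took 0.0239% to 0.0278% of counts in col-0, 0.0405% to 0.0467% in csld5 and 0.031% to 0.0428% in complemented libraries, and 96.9% of them came from 2 genes.

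Of the genes changed in csld5, 7430 moved back in the complemented line. Among 50 assignments of the 9 libraries, the real one included, the others gave at most 43. This argues against a random arrangement of these libraries as the source of the count. It cannot exclude a chance difference between plants or batches, since the libraries of a genotype may share these. For the single comparisons, the 10 splits of 6 libraries are too few for a share under 0.05: refitted on 6 libraries, the real splits gave 8596, 8544 and 451 genes and the highest others 0. A trend with GC content and gene length between the libraries was tested by correcting for it: a share kept of over 0.5 would have excluded the trend and one under 0.1 would have favoured it, a bound written after the results were seen, replaced for a time once the share was known, and then put back. The 3376 genes kept, of 7430, fall between, so this share decides nothing. After the correction 4697 genes moved back, against at most 62 in the same other assignments. Where these mix csld5 libraries with others, any feature shared by the csld5 libraries lowers the count, so the 62 does not bear on the trend. Counts simulated from the fitted curves alone gave 0 calls after the correction in both comparisons. Beside that 0, the 4697 argue against the fitted trend as the whole cause, but not against a bias that the curves miss. How much of the 7430 the trend accounts for stays open, since it cannot be told apart from an effect of genotype there. The csld5 libraries also stand apart on the first principal component (49.7% of variance), and a preparation batch shared by them could give the same picture, so that genotype and batch cannot be told apart.

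A run of 22 neighbouring genes on chromosome 1 was lower in csld5 and in complemented than in col-0 plants. Its median stayed at -1.63 after the GC and length correction, which argues against that trend, and the lowest library kept 32.5% of the col-0 level, which argues against complete loss of the segment in csld5. The ratio of col-0 to complemented had a median of 3.03 over the run (quartiles 2.89 and 3.19) and a spread of 0.11 on the log2 scale, against 0.15 for the 10 genes on each side. The ratio of col-0 to csld5 varied more, with a median of 3.07 (quartiles 2.66 and 3.45) and a spread of 0.43 against 0.38 beside the run, and 12 of the 22 genes (7 of the 20 beside it) differed between complemented and csld5 (edgeR). A candidate explanation is that the col-0 plants used here carried more copies of this segment than the csld5 and complemented plants, a difference of plant stock and not of CSLD5; DNA from these plants was not analysed here, a difference in the regulation of the segment was not tested, and neither ratio shows that a single factor holds for each gene.

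Chloroplast-encoded transcripts were lower in csld5 (median -1.93, quartiles -2.84 and -1.24) than in col-0, and higher again in the complemented line. They took at most 0.0329% of the counts of a library, and 0.00734% to 0.00815% in csld5. Less green tissue would lower nuclear photosynthesis genes in csld5 and raise them in the complemented line, but their medians were 0.18 (quartiles 0.04 and 0.34) and -0.32 (-0.43 and -0.15), and GC content alone would move nuclear genes as poor in GC as the chloroplast genome (36.3%) as far, but 761 such genes had medians of -0.49 (-0.85 and -0.19) and 0.59 (0.29 and 0.95), against -1.93 and 2.18 for the chloroplast. The 761 genes were chosen on GC content and an average log2 CPM of at least 1, a limit not set for the chloroplast genes. They were not matched on length. Lower carry-over of organelle RNA would lower mitochondrial transcripts in csld5 as far as the chloroplast ones, but the 9 tested had a median of -0.26 (quartiles -0.62 and 0.47). With 96.9% of mitochondrial reads in 2 genes, this median rests mostly on genes with few reads and is a weak test. The mitochondrial share of counts was higher in csld5 (0.0405% to 0.0467%) than in col-0 (0.0239% to 0.0278%). In the complemented line the 9 mitochondrial genes rose by a median of 1.02 (quartiles 0.20 and 1.29), so that carry-over cannot be told apart from other causes of the return. An effect of CSLD5 on chloroplast transcripts stays possible as a hypothesis. So do a bias with GC content and length together and a batch of RNA selection shared by the csld5 libraries, which were not tested.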
